A study of Sus scrofa with 54 samples.

How the data were processed

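Granulation tissue from 9 Yucatan minipigs was profiled by RNA sequencing, with 6 disk types in each pig and 3 pigs each at 4, 8 and 16 weeks, 54 libraries in all. Per the labels' protocols, total RNA was extracted with a kit for fibrous tissue, ribosomal RNA was removed, and stranded libraries were made. The deposited values are raw counts per gene, which the submitters' processing notes tie to STAR, an aligner, and featureCounts, a read counter. Their versions, the genome build, the annotation and the strand setting are not given in the sources used here. Reads of overlapping or antisense genes, or of near-identical copies such as members of the keratin and histone families, therefore cannot be told apart, and no genomic positions are printed.

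The table held 31908 genes under Ensembl identifiers, of which 15029 were paired with a symbol and 16879 were not. All columns matched 1 sample each. Total counts ran from 896521 to 34885901 with a median of 21674842, and a median of 19241.5 genes had at least 1 count. No 2 of the 54 libraries matched within counting noise, since the smallest chi-square per degree of freedom between any 2, of the same group or not, was 23.5.

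Tests used edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood F test, TMM normalization and Benjamini-Hochberg adjustment at 0.05. Genes were kept by edgeR's filter on expression over the 18 groups, which left 16988 genes within pigs (12921 with a symbol). The design had a column for each of the 9 pigs as a block and, within each time, a column for each disk type other than smooth control, 24 columns with 30 residual degrees of freedom. Coatings and textures were compared within pigs, averaged over the other factors, at each time, and as differences between textures and times. Times were compared on counts summed per pig, 3 pigs against 3, with 6 residual degrees of freedom over 18424 genes (13357 with a symbol). In all, 27 comparisons were made. The standard error of a log2 fold change was its size divided by the square root of F. CPM values are given as the mean ± SD over pigs after averaging the libraries of a pig. The common biological coefficient of variation was 0.44, and the lowest normalization factor was 0.11, in the shallowest library.

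The samples were paired by animal, since the labels give the pig of each library. After group means were removed, libraries of the same pig had a median correlation of 0.085 at 4 weeks, 0.098 at 8 weeks and 0.079 at 16 weeks, against −0.045, −0.03 and −0.073 between pigs.

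Gene lists were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, then with an estimated correlation and with fry. There were 32 lists with 576 entries for cell types, pathways and signs of handling, and a list needed at least 5 measured members. A list score is the mean log2 CPM of its measured members, with a prior count of 2. The designs, tests, lists, alternatives and the rule for named genes were set before the data were examined. Under that rule the text names, among genes with an adjusted p under 0.05, a symbol and a mean of at least 1 log2 CPM, the 6 highest and 6 lowest fold changes that kept their direction in at least 8 of 9 pigs or, over time, had no overlap between pigs. It adds up to 2 called genes per list, the 5 smallest p-values where fewer than 6 genes passed, up to 2 per direction within a single texture and time, and 18 marker genes, of which 13 were named in the table. Its use at 4 and 16 weeks for porous against smooth disks was decided after the data were seen, as were the list tests at each time. A few genes that the rule names are not reported here. Which marker genes are quoted where they did not pass was also chosen after their values were seen.

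The alternatives set beforehand were DESeq2 1.42.0, limma-voom with quality weights, DESeq2's size factors in edgeR, no filter, a stricter filter (CPM of at least 1 in 27 libraries, or in 5 pigs), no pig block, the libraries of 1 time alone, each pig left out, only control disks over time, and limma-voom with pigs as a random effect (consensus correlation 0.067). The following 4 were added after seeing the data: leaving out the 2 shallowest libraries, leaving out the library with the most detected genes, leaving out the library with the lowest collagen score, and a keratinocyte score as covariate. Chance was examined by refitting other splits of the libraries, at most 25 with the real one. The number drawn over time was lowered after larger draws had been seen.

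The tests were checked on simulated counts with 100 genes changed at each of 2 fold sizes. The simulated genes varied independently, with no pig effects and no shared differences in tissue content, so the shares below may not hold for the real libraries. With the labels of the real libraries shuffled, up to 1415 genes were called for gKOS against control and up to 949 for porous against smooth disks. For gKOS against control, 72% of 2-fold and 94% of 4-fold changes were recovered, and 5.3% of calls were false. For porous against smooth disks the values were 74%, 96% and 7.6%, for gKOS against control on smooth disks at 8 weeks 22%, 58% and 2.4%, and for 16 against 4 weeks 39%, 69% and 7.7%. Intervals on counts cover counting error only.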

Results

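RNA was sequenced from granulation tissue, the new vascular connective tissue of a healing wound, collected at devices that cross the skin of Yucatan minipigs, a small breed used as a model of human skin. Each device had a disk under the skin that was either smooth or porous. The disk was a control or carried 1 of 2 treatments labelled gKOS and iKTN. The series concerns keratin nanomaterials as coatings, and the 2 names are not spelled out in the sources used here. All 9 pigs carried all 6 disk types, and 3 pigs each were examined at 4, 8 and 16 weeks, which gave 54 libraries in 18 groups of 3. Every disk type had the same device number in all 9 pigs, so neither coating nor texture can be separated from the device number.

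Total counts per library ran from 896521 to 34885901 with a median of 21674842. Only 2 libraries were far below the rest, and the third lowest held 8764699 counts. The shallowest, from the smooth iKTN disk of pig 17 at 4 weeks, held 896521 counts, of which MOB2 took 81.3% (95% Clopper-Pearson interval 81.3 to 81.4%, counting error only). The other, from the porous gKOS disk of pig 18 at 4 weeks, held 1663721 counts. The smooth control library of pig 16 at 4 weeks stood apart in composition, with a mean of 7.18 log2 CPM over a list of fibrillar collagen and matrix genes, against at least 8.85 in the other libraries.

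The first comparison asked which transcripts differed between gKOS and control disks, averaged over both textures and all 3 times within each pig. HOXA10 and HOXA9, homeobox transcription factors that carry positional identity in limb and trunk tissue, were lower at gKOS disks in 9 of 9 pigs. HOXA10 (ENSSSCG00000021204) averaged 0.361 ± 0.368 CPM (SD, n = 9 pigs) at gKOS disks and 2.37 ± 1.26 CPM at control disks, a log2 fold change of −3.59 (SE 0.271, edgeR adjusted p = 1.26e-10). HOXA9 (ENSSSCG00000028997) averaged 2.37 ± 1.21 CPM against 6.12 ± 2.48 CPM, a log2 fold change of −1.47 (SE 0.225, edgeR adjusted p = 0.00161). No other gene of the 16988 tested passed, while 2011 had an unadjusted p under 0.05. Without pig 17, HOXA9 stood at −1.41 and no longer passed (edgeR adjusted p = 0.0805). Among the genes with the next smallest p-values, HOXC8, another homeobox factor, had 8.33 ± 5.27 CPM against 3.86 ± 0.95 CPM (log2 1.07, edgeR adjusted p = 0.339). HOXC10 had a log2 fold change of −2.78 (edgeR adjusted p = 0.283) and the myosin light chain gene MYL10 one of 2.48 (edgeR adjusted p = 0.339).

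Among gene lists fixed beforehand, keratinocyte genes, which encode the keratins and adhesion proteins of the epidermis, had the largest shift at gKOS disks. All 17 measured members had positive values with a median log2 fold change of 2.63, 14 passed when adjusted over the list alone, and 0 passed over all genes. The keratinocyte score (mean log2 CPM of the list) was 4.71 ± 2.29 at gKOS disks and 2.19 ± 1.88 at control disks (SD, n = 9 pigs), higher in 8 of 9 pigs. The keratinocyte list was called by camera (adjusted p = 4.04e-16), and the call was lost at adjusted p = 0.35 with an estimated correlation. Collagen and matrix genes had positive values in 27 of 29 members (median 0.57), of which 4 passed when adjusted over the list alone (camera adjusted p = 4.19e-15, adjusted p = 0.35 with an estimated correlation). COL1A1, the main chain of type I collagen, had 33700 ± 18800 CPM against 18310 ± 6680 CPM and did not pass (log2 0.95, edgeR adjusted p = 0.339). Macrophage genes had negative values in 14 of 17 members (median −0.42), of which 3 passed when adjusted over the list alone (camera adjusted p = 1.38e-05, adjusted p = 0.35 with an estimated correlation). Without the library of lowest collagen score, a control, the macrophage median was −0.26 and camera still called the list (adjusted p = 0.000106). The collagen and matrix median was then 0.46 (camera adjusted p = 2.08e-13). Adipocyte genes had a median of −0.60 (camera adjusted p = 0.000103, adjusted p = 0.35 with an estimated correlation). Mitochondrially encoded genes of oxidative phosphorylation had positive values in 13 of 13 members with a median of 0.49 (camera adjusted p = 1.36e-05, adjusted p = 0.35 with an estimated correlation), which was 0.27 without the 2 shallowest libraries (camera adjusted p = 0.00273). Of the 32 lists, camera called 10 up and 6 down, and 0 were called with an estimated correlation.

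**Figure D1:**
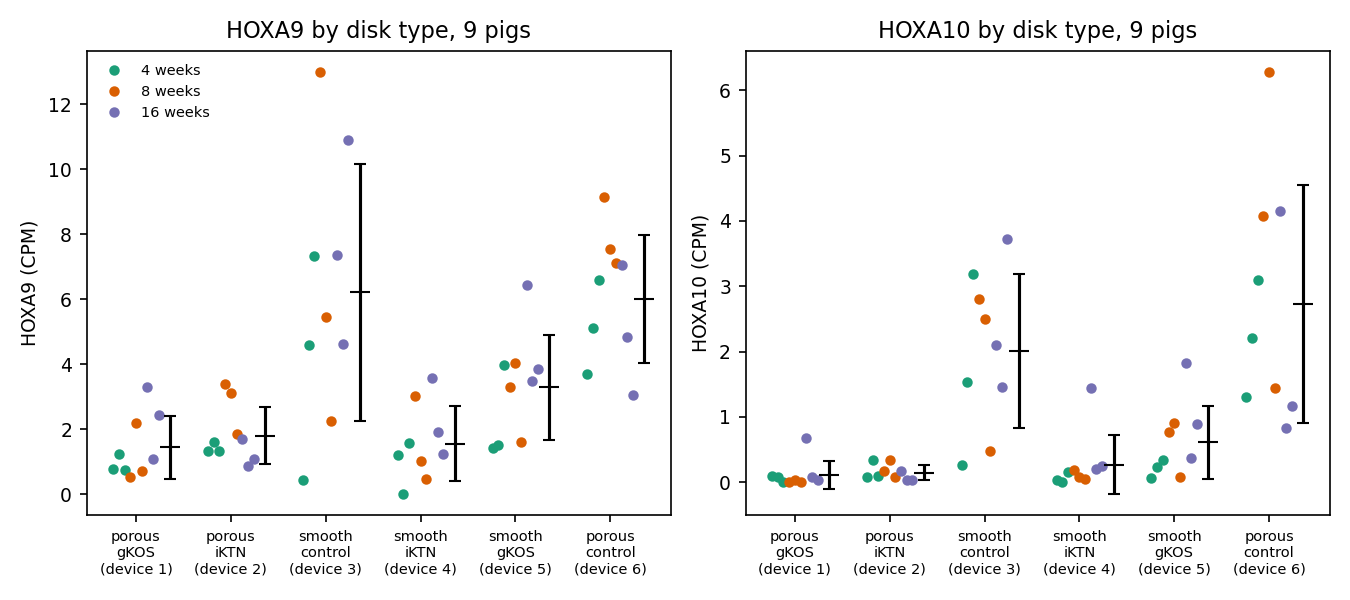
HOXA9 and HOXA10 in CPM for each of the 9 pigs by disk type, with weeks as colours and the mean ± SD beside the points; the device number stands under each disk type. HOXA10 averaged 2.37 CPM over the control disks, 0.361 CPM over the gKOS disks and 0.209 CPM over the iKTN disks.

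The same question was asked of iKTN against control disks. HOXA10 and HOXA9 were again lower at the coated disks in 9 of 9 pigs. HOXA10 averaged 0.209 ± 0.23 CPM (SD, n = 9 pigs) at iKTN disks against 2.37 ± 1.26 CPM at control disks, a log2 fold change of −3.85 (SE 0.276, edgeR adjusted p = 2.62e-11). HOXA9 averaged 1.68 ± 0.792 CPM against 6.12 ± 2.48 CPM, a log2 fold change of −1.79 (SE 0.232, edgeR adjusted p = 5.45e-05). These were the 2 genes that passed, and 1518 genes had an unadjusted p under 0.05. HOXC8 did not pass, with 8.42 ± 3.31 CPM against 3.86 ± 0.95 CPM (log2 1.12, edgeR adjusted p = 0.535). INTU, a gene of primary cilium assembly, had a log2 fold change of −0.56 (edgeR adjusted p = 0.535), and PAGE4 one of −1.91 (edgeR adjusted p = 0.535).

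Collagen and matrix genes had positive values in 29 of 29 members at iKTN disks, with a median of 0.54 (camera adjusted p = 2.17e-18, adjusted p = 0.433 with an estimated correlation). COL1A1 had 30480 ± 11000 CPM against 18310 ± 6680 CPM and did not pass (log2 0.83, edgeR adjusted p = 0.551). Mitochondrially encoded genes of oxidative phosphorylation had positive values in 13 of 13 members with a median of 0.49, of which 2 passed when adjusted over the list alone (camera adjusted p = 7.26e-08, adjusted p = 0.502 with an estimated correlation). Hypoxia and glycolysis genes had negative values in 15 of 15 members with a median of −0.47 (camera adjusted p = 0.000295, adjusted p = 0.502 with an estimated correlation). Immediate early and handling stress genes, which respond within minutes to dissection, had negative values in 21 of 23 members with a median of −0.31 (camera adjusted p = 0.000975, adjusted p = 0.502 with an estimated correlation). Macrophage genes had a median of −0.42 (camera adjusted p = 0.00117, adjusted p = 0.502 with an estimated correlation). Without the library of lowest collagen score, a control, these medians were −0.23 for hypoxia and glycolysis (camera adjusted p = 0.0106), −0.19 for immediate early and handling stress (camera adjusted p = 0.00894) and −0.28 for macrophage genes (camera adjusted p = 0.00795). The collagen and matrix median was then 0.44 (camera adjusted p = 9.82e-18). Keratinocyte genes had a median of 0.45 and were not called (camera adjusted p = 0.216). Camera called 7 lists up and 7 down, and 0 with an estimated correlation.

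Between the 2 coatings, gKOS minus iKTN, the keratinocyte list again had the largest shift. Its members had values higher at gKOS disks in 16 of 17 cases with a median of 2.27 (camera adjusted p = 2.44e-24, adjusted p = 0.167 with an estimated correlation). Adipocyte genes had values lower at gKOS disks in 16 of 17 members with a median of −0.55 (camera adjusted p = 7.12e-07, adjusted p = 0.369 with an estimated correlation), which was −0.34 without the 2 shallowest libraries (camera adjusted p = 0.000887). Immediate early and handling stress genes had a median of 0.23 (camera adjusted p = 9e-08, adjusted p = 0.215 with an estimated correlation). Complement genes, which encode a plasma defence cascade, had a median of −0.22 (camera adjusted p = 0.000231, adjusted p = 0.215 with an estimated correlation). Hypoxia and glycolysis genes had a median of 0.12 (camera adjusted p = 0.0399, adjusted p = 0.977 with an estimated correlation). No single gene passed in edgeR (0 genes), while 415 had an unadjusted p under 0.05, DESeq2 called 11 and limma-voom 0. The genes with the smallest p-values included TPPP, which encodes a tubulin-binding protein (log2 0.90), the growth factor gene FGF10 (log2 −0.92) and the chemokine receptor gene CX3CR1 (log2 −0.78), each at an edgeR adjusted p of 1. MOB2, also among them at −2.69, stood at 0.08 without the 2 shallowest libraries.

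Within single textures and times, with 3 pigs on each side, HOXA10 was the gene that passed most often. It was lower at porous gKOS disks at 4 weeks (log2 −4.31, edgeR adjusted p = 0.0242) and at porous iKTN disks at 4 weeks (log2 −3.76, edgeR adjusted p = 0.0337). At 8 weeks it was lower at porous iKTN disks (log2 −4.30, edgeR adjusted p = 0.00164) and at smooth iKTN disks (log2 −3.97, edgeR adjusted p = 0.0184). At porous gKOS disks at 8 weeks the 3 libraries held 1 HOXA10 count in all, against 244 in the controls (edgeR adjusted p = 1.32e-06). The ratio scaled by library size was 0.00349, with a 95% interval of 8.79e-05 to 0.0196 for counting error only. At 16 weeks HOXA10 was lower at porous iKTN disks (log2 −4.70, edgeR adjusted p = 0.0008), as was PSEN2, which encodes a catalytic subunit of gamma-secretase, with 21.5 ± 2.73 CPM against 67.8 ± 37.7 CPM (SD, n = 3 pigs; log2 −1.61, SE 0.279, edgeR adjusted p = 0.0159). MOB2 passed for smooth iKTN at 4 weeks (log2 16.3, edgeR adjusted p = 0.0126) through the shallowest library, and stood at −0.24 without the 2 shallowest libraries. Of the HOXA10 calls, that for porous gKOS at 8 weeks passed without any 1 pig and without the pig block, while the others kept their direction and ended without the block. They also ended without pig 16, 17, 18, 07, 08 or 04 and without the 2 shallowest libraries (porous disks at 4 weeks), without pig 17, 06, 07, 08 or 04 (smooth iKTN at 8 weeks), without pig 06, 07 or 08 (porous iKTN at 8 weeks) or without pig 04 (porous iKTN at 16 weeks), and PSEN2 did without pig 06, 07, 08, 04 or 05.

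The other single comparisons called 0 genes in edgeR. They were gKOS on smooth disks at 4 weeks (1878 genes at an unadjusted p under 0.05, DESeq2 88, limma-voom 0), 8 weeks (1068, DESeq2 8, limma-voom 0) and 16 weeks (458, DESeq2 17, limma-voom 0). The same held for iKTN on smooth disks at 16 weeks (227 genes at an unadjusted p under 0.05, DESeq2 2, limma-voom 2) and gKOS on porous disks at 16 weeks (1933, DESeq2 143, limma-voom 677). The gKOS minus control value of HOXA10 differed by texture, at a log2 fold change of −5.10 on porous and −2.07 on smooth disks, a difference of −3.03 (edgeR adjusted p = 0.0363). Porous gKOS was device 1 and smooth gKOS device 5 in all 9 pigs, so this difference cannot be told apart from one of device place. This HOXA10 difference did not pass under DESeq2's size factors, without the 2 shallowest libraries, without the pig block, or without any 1 pig except pig 81. The iKTN effect differed by texture for 0 genes in edgeR (884 at an unadjusted p under 0.05, DESeq2 17, limma-voom 0). Over the 3 times, the gKOS effect differed for 0 genes in edgeR (2068 at an unadjusted p under 0.05, DESeq2 8, limma-voom 0) and the iKTN effect for 0 (860, DESeq2 1, limma-voom 0).

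The responses to gKOS and to iKTN were set against each other across genes, which are not independent replicates. HOXA10 and HOXA9 were the 2 genes called in both. Unchanged libraries, with the controls simulated too, shared 0, and independent lists, a figure that ignores the shared controls, would share 0.000235. Pearson's r of the 2 sets of fold changes was 0.672 and Spearman's rho 0.712. Unchanged libraries, simulated in 4 runs with each gene drawn independently, gave a mean r of 0.475 and rho of 0.437, because both comparisons share their simulated controls. The covariance was 0.111, against 0.0437 simulated. To share no library, gKOS minus control on smooth disks was set against iKTN minus control on porous disks, and the reverse. The first gave an r of −0.27 and a rho of 0.0939, the second 0.225 and 0.410, where the simulated rho lay from −0.0121 to 0.0113. The simulated r lay from −0.026 to 0.0202, and the observed r fell outside it on opposite sides. In these 2 pairings texture and device number differ along with the coating, which the simulation does not hold. It is also too narrow for genes that vary together, so it cannot decide whether the coatings share a response. Without pig 16 the shared-control r was 0.362.

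Porous and smooth disks were compared within each pig, averaged over coatings and times, to ask which transcripts differed between them. ACTG2, a smooth muscle actin, was lower at porous disks, with 13.95 ± 12.4 CPM against 77.9 ± 68.6 CPM (SD, n = 9 pigs; log2 −2.19, SE 0.423, edgeR adjusted p = 0.00763). THBS1, a matrix glycoprotein that activates TGF-beta, had 687 ± 201 CPM against 1476 ± 469 CPM (log2 −1.16, SE 0.207, edgeR adjusted p = 0.00398), and LTBP2, a latent TGF-beta binding protein, fell by 1.36 on the log2 scale (edgeR adjusted p = 0.0241). CHRDL1 (ENSSSCG00000012576), a secreted antagonist of bone morphogenetic proteins, had 7.75 ± 3.55 CPM at porous disks against 46.2 ± 21.2 CPM at smooth disks, lower in 9 of 9 pigs (log2 −2.67, SE 0.264, edgeR adjusted p = 1.75e-07). The homeobox gene DLX2 (log2 −3.22, SE 0.439, edgeR adjusted p = 0.000164) and the matrix gene ADAMTSL3 (log2 −2.26, SE 0.374, edgeR adjusted p = 0.00193) were also lower in 9 of 9 pigs. Also lower were CCN5 (log2 −1.74), EFHD1 (log2 −1.64) and the calcium channel gene RYR3 (log2 −1.61). The macrophage receptor genes VSIG4 (log2 −0.65), MARCO (log2 −1.21) and C3AR1 (log2 −0.60) were lower as well. GATA3, a transcription factor of T cells and of epidermis, was higher at porous disks (log2 1.37, SE 0.244, edgeR adjusted p = 0.00398). So were SP6 (log2 1.89), DAPL1 (log2 1.74) and GDA (log2 1.65), as well as ZSWIM2 (log2 1.70) and UGT8 (log2 1.51). In all, 77 genes were higher and 79 lower, 156 together, and 2482 had an unadjusted p under 0.05.

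As groups, myofibroblast and smooth muscle genes had negative values at porous disks in 14 of 14 members (median −0.64), of which 12 passed when adjusted over the list alone (camera adjusted p = 3.41e-14, adjusted p = 0.351 with an estimated correlation). T cell genes had positive values in 18 of 18 members with a median of 0.53 (camera adjusted p = 8.45e-06, adjusted p = 0.462 with an estimated correlation). Proliferation genes had positive values in 18 of 18 with a median of 0.26 (camera adjusted p = 3.84e-06, adjusted p = 0.395 with an estimated correlation). Interferon response genes had negative values in 21 of 21 with a median of −0.26 (camera adjusted p = 7.27e-06, adjusted p = 0.391 with an estimated correlation). By time the interferon median was −0.29 at 4 weeks (camera adjusted p = 0.00235, adjusted p = 0.806 with an estimated correlation), −0.69 at 8 weeks and 0.22 at 16 weeks, where the list was not called (camera adjusted p = 0.212). Keratinocyte genes had positive values in 17 of 17 members with a median of 2.23, of which 12 passed when adjusted over the list alone (camera adjusted p = 9.4e-08, adjusted p = 0.391 with an estimated correlation). The keratinocyte score differed by 2.05 ± 3.80 (SD, n = 9 pigs, higher in 6 of 9), by 4.89 at 4 weeks, 1.53 at 8 weeks and −0.28 at 16 weeks, where it was higher at porous disks in 1 of 3 pigs and the list was not called (median −0.58, camera adjusted p = 0.56). The T cell score differed by 0.31 ± 0.71, −0.14 ± 1.38 and 1.58 ± 1.33 at the same times (SD, n = 3 pigs). Camera called 6 lists up and 8 down, and 0 with an estimated correlation. The gene count was 72 without the 2 shallowest libraries, 255 without the library of lowest collagen score and 23 with the keratinocyte score as a covariate. It lay from 22 to 97 without pig 07, 17, 18, 04 or 08 and from 323 to 623 without pig 05, 06 or 16.

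At 4 weeks, CD163, the haemoglobin scavenger receptor of macrophages, was lower at porous disks, with 214 ± 88.2 CPM at porous and 589 ± 246 CPM at smooth disks (SD, n = 3 pigs; log2 −1.34, SE 0.294, edgeR adjusted p = 0.0363). The scavenger receptor gene MARCO fell by 3.02 (SE 0.569, edgeR adjusted p = 0.0116), VSIG4 by 1.42 (edgeR adjusted p = 0.0244) and the inhibitory receptor gene CD200R1 by 1.57 (edgeR adjusted p = 0.0363) on the log2 scale. PPBP, a platelet chemokine, had 2.18 ± 0.739 CPM against 101.7 ± 77.3 CPM (log2 −4.75, SE 0.85, edgeR adjusted p = 0.0116). KRT10, a keratin of differentiating epidermis, had 5356 ± 4410 CPM against 257 ± 169 CPM (log2 5.84, SE 1.48, edgeR adjusted p = 0.0493). Without the 2 shallowest libraries KRT10 had 2182 ± 1100 CPM against 221 ± 219 CPM and did not pass (log2 5.31, edgeR adjusted p = 0.163). Also lower were AQP9 (log2 −2.62), TSPAN32 (log2 −2.29), CHRDL1 (log2 −2.20), the immediate early gene FOS (log2 −2.08), the complement gene C2 (log2 −1.31) and the endothelial receptor gene TIE1 (log2 −0.92). Also higher were WNT3 (log2 4.24), PRLR (log2 4.14), LYPD2 (log2 3.88) and DAPL1 (log2 3.22). Of the genes named here, MARCO, VSIG4, PPBP and AQP9 still passed without the 2 shallowest libraries and PPBP and CHRDL1 without the library of lowest collagen score, while the rest in each case kept their direction and did not pass. In all, 75 genes were higher and 68 lower, 143 together, and 3039 had an unadjusted p under 0.05. Under DESeq2's size factors the split was 117 higher and 57 lower.

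All 17 keratinocyte genes had positive values at 4 weeks with a median of 4.87; 1 passed over all genes and 17 when adjusted over the list alone (camera adjusted p = 4.73e-15, adjusted p = 0.268 with an estimated correlation). The keratinocyte score was 7.28 ± 1.23 at porous and 2.39 ± 2.60 at smooth disks (SD, n = 3 pigs). Macrophage genes had a median of −0.98, with 3 of 17 lower over all genes and 10 when adjusted over the list alone (camera adjusted p = 7.92e-10, adjusted p = 0.253 with an estimated correlation). The smooth control library of pig 16, that of lowest collagen score, had the highest macrophage score of all (9.07), and without it the median was −0.67 (camera adjusted p = 3.22e-08). Mitochondrially encoded genes of oxidative phosphorylation had a median of 1.13, with 11 of 13 higher when adjusted over the list alone (camera adjusted p = 7.06e-06, adjusted p = 0.731 with an estimated correlation). Without the 2 shallowest libraries that median was 0.51 (camera adjusted p = 0.00314). Genes of alternatively activated macrophages had a median of −0.61 (camera adjusted p = 7.47e-06, adjusted p = 0.253 with an estimated correlation). The gene count at 4 weeks was 14 without the 2 shallowest libraries, 14 without the library of lowest collagen score, 2, neither of them named here, in a fit of the 4-week libraries alone and 0 with the keratinocyte score as a covariate. It was 55 without the pig block, 437 without pig 06, a pig of another time that enters only through the shared fit, and from 3 to 98 without any other pig.

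**Figure D2:**
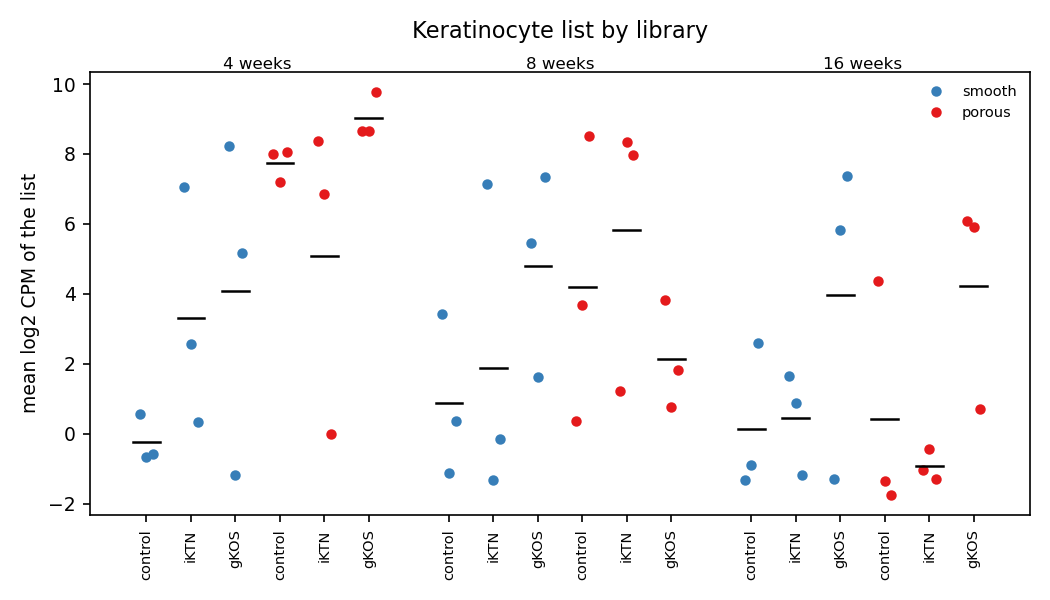
Mean log2 CPM of the keratinocyte list in each of the 54 libraries, by week, texture and coating; points are libraries, bars are group means. At 4 weeks the score per pig averaged 7.28 at porous disks and 2.39 at smooth disks.

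At 8 weeks the interferon response genes, which are switched on by antiviral cytokines, had negative porous-minus-smooth values in 21 of 21 members. Their median was −0.69, and 4 passed when adjusted over the list alone (camera adjusted p = 1.5e-19, adjusted p = 0.197 with an estimated correlation). Myofibroblast and smooth muscle genes had a median of −0.43 (camera adjusted p = 5.73e-06, adjusted p = 0.518 with an estimated correlation) and adipocyte genes one of −0.55 (camera adjusted p = 0.000275, adjusted p = 0.518 with an estimated correlation). Keratinocyte genes had a median of 2.62 (camera adjusted p = 5.73e-06, adjusted p = 0.518 with an estimated correlation). These medians depended on single pigs, since without pig 07 they were −0.25 for interferon response and 1.02 for keratinocyte genes, and without pig 08 the adipocyte one was 0.01. No single gene passed in edgeR (0 genes), with 757 at an unadjusted p under 0.05, 20 called by DESeq2 and 216 by limma-voom.

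At 16 weeks, CD3D, a chain of the T cell receptor complex, was higher at porous disks, with 44.95 ± 17.1 CPM at porous and 11.3 ± 5.07 CPM at smooth disks (SD, n = 3 pigs; log2 1.98, SE 0.47, edgeR adjusted p = 0.019). Of 18 T cell genes, 15 were higher over all genes and 18 when adjusted over the list alone, with a median log2 fold change of 1.58 (camera adjusted p = 2.04e-12, adjusted p = 0.441 with an estimated correlation). The others of this kind included CD3E (log2 1.95) and CD247 (log2 1.82), also of the receptor complex. Of 16 B and plasma cell genes, 2 passed over all genes, the kinase gene BLK (log2 2.07) and the transcription factor gene PAX5 (log2 2.26). Also higher were CD1E (log2 2.74), CCR7 (log2 1.71), FLT3 (log2 1.31), IL12B (log2 2.35), CD40 (log2 0.98) and TNFRSF9 (log2 2.60). Of 11 MHC class II and antigen presentation genes, 3 were higher over all genes and 9 when adjusted over the list alone (median 0.90, camera adjusted p = 1.45e-05, adjusted p = 0.441 with an estimated correlation). Proliferation genes had positive values in 18 of 18 members with a median of 0.60, of which 14 passed when adjusted over the list alone (camera adjusted p = 1.22e-08, adjusted p = 0.441 with an estimated correlation). The mitotic checkpoint genes BUB1B (log2 0.81) and BUB1 (log2 0.81) were among those that passed over all genes. The T cell score differed by 3.09 in pig 04, 1.08 in pig 81 and 0.58 in pig 05. Without pig 04 only CHRDL1 still passed at 16 weeks, and the list medians were 0.73 for T cells and 0.49 for MHC class II and antigen presentation.

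In the same comparison, 28 of 29 collagen and matrix genes had negative values with a median of −0.92. Over all genes 7 were lower and 1 higher, and when adjusted over the list alone 18 were lower and 1 higher (camera adjusted p = 1.22e-08, adjusted p = 0.444 with an estimated correlation). The collagen score differed by −0.89 ± 0.90 (SD, n = 3 pigs), by −1.88 in pig 04, −0.69 in pig 05 and −0.11 in pig 81, and the list median was −0.48 without pig 04. COL1A1 was lower (log2 −1.46, SE 0.458, edgeR adjusted p = 0.0452), and COL11A1, a minor fibrillar collagen, had 488 ± 334 CPM at porous and 1469 ± 487 CPM at smooth disks (SD, n = 3 pigs; log2 −2.44, edgeR adjusted p = 0.0214). The large proteoglycan gene VCAN (log2 −1.39), the collagen gene COL6A6 (log2 −3.82) and the tendon gene TNMD (log2 −4.76) were lower too. Myofibroblast and smooth muscle genes had a median of −1.01, and 6 of 14 were lower over all genes and 10 when adjusted over the list alone (camera adjusted p = 5.12e-06, adjusted p = 0.443 with an estimated correlation). They included the actin genes ACTA2 (log2 −1.57) and ACTG2 (log2 −2.82) and the calponin gene CNN1 (log2 −1.72). Genes of foreign body giant cells and osteoclasts, which are fused macrophages, had a median of 1.23, and 6 of 12 were higher over all genes and 8 when adjusted over the list alone (camera adjusted p = 8.37e-05, adjusted p = 0.441 with an estimated correlation). MMP9, a gelatinase of such cells, had 1301 ± 597 CPM against 279 ± 164 CPM (log2 2.22, edgeR adjusted p = 0.0246). The mannose receptor gene MRC1 (log2 1.36) was higher as well, while the complement genes C1QB (log2 −1.39) and C1QA (log2 −1.15), made by macrophages, and the folate receptor gene FOLR2 (log2 −1.52) were lower.

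CHRDL1 (log2 −3.60, SE 0.469, edgeR adjusted p = 0.00012), ADAMTSL3 (log2 −3.66), DLX2 (log2 −3.29), SLITRK6 (log2 −3.06) and the Schwann cell cadherin gene CDH19 (log2 −4.58) were also lower at porous disks at 16 weeks. The myelin gene MBP (log2 1.31), NPTX1 (log2 2.36), NYAP2 (log2 2.65) and the transporter gene SLC22A3 (log2 2.54) were higher. In all, 616 genes were higher and 805 lower, 1421 together, and 4753 had an unadjusted p under 0.05. Under DESeq2's size factors the split was 513 higher and 1016 lower. Camera called 11 lists up and 3 down, and 0 with an estimated correlation. The gene count was 305 without pig 05, 627 without pig 07, 926 without the pig block and 6, none of them named here, in a fit of the 16-week libraries alone.

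**Figure D3:**
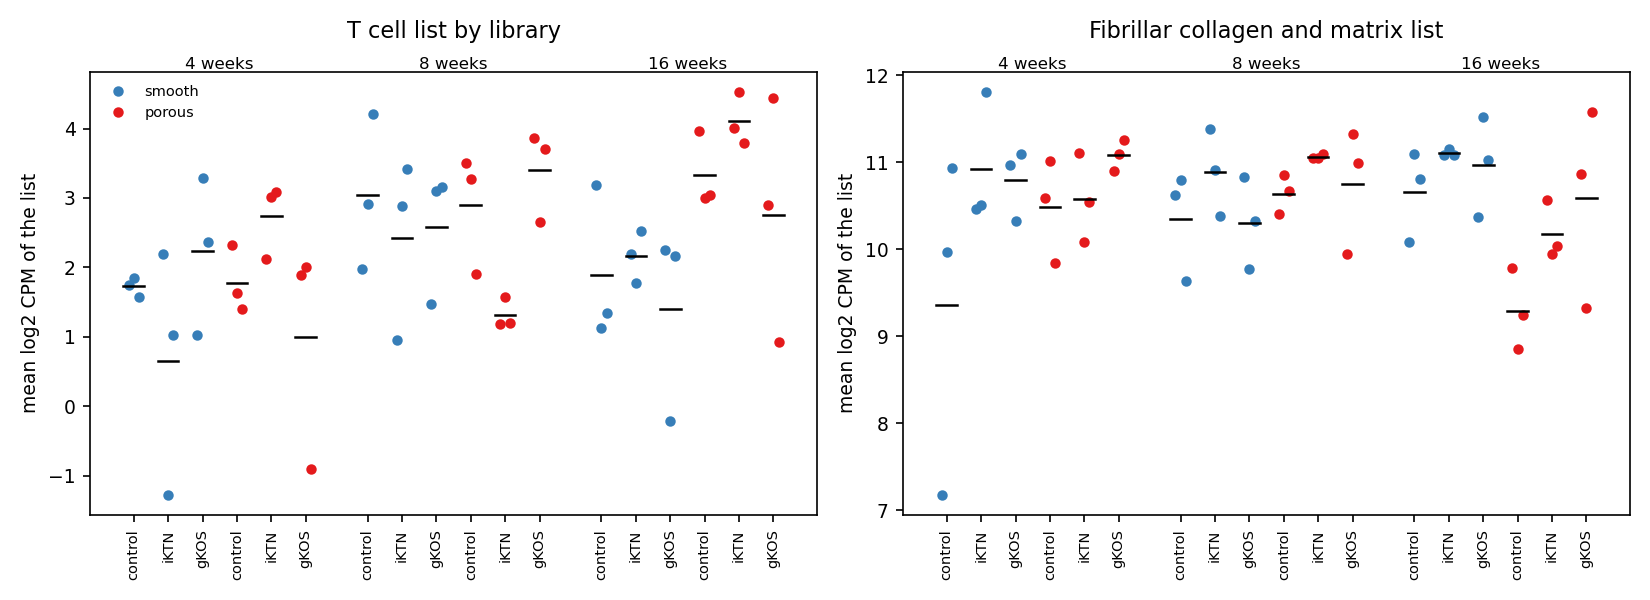
Mean log2 CPM of the T cell list (left) and of the collagen and matrix list (right) in each of the 54 libraries, by week, texture and coating; points are libraries, bars are group means. At 16 weeks the T cell score per pig averaged 3.40 at porous and 1.82 at smooth disks, and the collagen score 10.02 and 10.91.

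The texture effect itself differed between the 3 times for 471 genes, and 3875 had an unadjusted p under 0.05. Of these 471, 51 had passed at 4 weeks, 0 at 8 weeks in edgeR and 315 at 16 weeks, and 457 had opposite signs at 4 and 16 weeks. Choosing genes by a difference between times favours opposite signs, so the 457 are no separate evidence of a reversal. The macrophage gene MARCO had porous-minus-smooth log2 fold changes of −3.02, −0.80 and 0.20 at 4, 8 and 16 weeks (edgeR adjusted p of the difference = 0.0429), and PPBP had −4.75, −1.67 and 0.10 (edgeR adjusted p = 0.039). The Schwann cell gene CDH19 had 1.67, 0.38 and −4.58 (edgeR adjusted p = 0.0493), and the complement gene C1QA had 0.12, 0.52 and −1.15 (edgeR adjusted p = 0.0389). Of the genes called at 4 and at 16 weeks, 11 were shared, 5 of them in the same direction, where independent lists would share 12. The count was 264 without the 2 shallowest libraries, 164 without the library of lowest collagen score, 193 without the pig block and 0 with the keratinocyte score as a covariate. It was 0 without pig 16, 07, 08, 04 or 05, 9 without pig 17, and from 772 to 1675 without pig 81, 18 or 06.

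Over time, the counts of each pig were summed and pigs of different weeks were compared, which mixes the week with the animals. Between 4 and 16 weeks MMP1, an interstitial collagenase, rose from 52.5 ± 7.42 CPM at 4 weeks to 1039 ± 300 CPM at 16 weeks (SD, n = 3 pigs; log2 4.31, SE 0.606, edgeR adjusted p = 0.0342). The collagenase gene MMP13 (log2 2.97), the neutrophil and epithelial lipocalin gene LCN2 (log2 3.09) and the complement gene C3 (log2 1.64) rose too. The T cell genes CTLA4 (log2 1.90) and CD3E (log2 1.38) rose, as did the antigen presentation genes FLT3 (log2 1.04) and CCR7 (log2 1.36). ITIH4 (log2 2.88, edgeR adjusted p = 0.0187), the melanocyte gene MLANA (log2 2.95) and CUX2 (log2 2.06) rose as well. The epidermal genes CDSN (log2 −3.58, edgeR adjusted p = 0.0435), CALML5 (log2 −3.52), KLK5 (log2 −3.45), ASPRV1 (log2 −3.36), CST6 (log2 −3.23), KRTDAP (log2 −3.02), KRT80 (log2 −2.27) and PERP (log2 −2.34) fell. The hair follicle regulators HOXC13 (log2 −3.34) and FOXN1 (log2 −2.95) fell, as did the erythroid haem synthesis gene ALAS2 (log2 −2.86) and the chaperone gene DNAJB1 (log2 −0.74). In all, 81 genes rose and 193 fell, 274 together, and 4186 had an unadjusted p under 0.05.

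Matrix proteases and their inhibitors had positive 16-minus-4-week values in 14 of 19 members (median 0.53), of which 2 passed over all genes (camera adjusted p = 0.00189, adjusted p = 0.647 with an estimated correlation). T cell genes had positive values in 18 of 18 members (median 1.03), of which 2 passed over all genes and 11 when adjusted over the list alone (camera adjusted p = 3.44e-13, adjusted p = 0.587 with an estimated correlation). Keratinocyte genes had negative values in 17 of 17 members (median −2.43), of which 3 passed over all genes and 14 when adjusted over the list alone (camera adjusted p = 1.73e-17, adjusted p = 0.587 with an estimated correlation). The 6 genes CDSN, ASPRV1, CST6, KRTDAP, KRT80 and PERP had the opposite sign when smooth control disks alone were compared, with values from 1.62 to 5.36 on the log2 scale, and did not pass there (edgeR adjusted p = 0.778). The count was 0 over smooth control disks alone (DESeq2 and limma-voom were not run on this subset), 0 without pig 16 or 18, from 1 to 23 without pig 17, 81, 04 or 05, and 758 without pig 08.

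Between 8 and 4 weeks, T cell genes had a median of 0.77, with 17 of 18 positive and 9 passing when adjusted over the list alone (camera adjusted p = 9.48e-10, adjusted p = 0.748 with an estimated correlation). Proliferation genes had a median of −0.31 (camera adjusted p = 7.27e-05, adjusted p = 0.748 with an estimated correlation) and keratinocyte genes one of −0.82 (camera adjusted p = 0.000374, adjusted p = 0.748 with an estimated correlation). No gene passed in edgeR (0 genes), with 2664 at an unadjusted p under 0.05, 746 called by DESeq2 and 466 by limma-voom. The smallest adjusted p was 0.0598, shared by WDR83OS (log2 −0.93), the small nucleolar RNA gene SNORA48 (log2 −2.07) and the ribosomal protein gene RPL36A (log2 −0.76). Between 16 and 8 weeks, keratinocyte genes had a median of −1.71, with 11 passing when adjusted over the list alone (camera adjusted p = 1.65e-16, adjusted p = 0.747 with an estimated correlation). Genes of foreign body giant cells and osteoclasts had a median of 0.80 (camera adjusted p = 2.76e-05, adjusted p = 0.858 with an estimated correlation) and adipocyte genes one of −0.79 (camera adjusted p = 2.34e-05, adjusted p = 0.858 with an estimated correlation). No gene passed in edgeR (0 genes), with 1679 at an unadjusted p under 0.05, 276 called by DESeq2 and 0 by limma-voom. GSTO2, a glutathione transferase gene, had the smallest p (log2 5.17, edgeR adjusted p = 0.165), followed by ITIH4 (log2 1.99, edgeR adjusted p = 0.165).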

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

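The tests of the 2 shallowest libraries, of keratinocyte content and of the size of the folds were chosen only after the results were seen. The test of rows or sides was fixed before.

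The texture effect differed between the 3 times for 471 genes, which is a tested difference between groups. Among the genes lower at porous disks at 4 weeks and not at 16 weeks, the adjusted p of the difference in edgeR was 0.0429 for MARCO, 0.039 for PPBP, 0.0391 for AQP9, 0.0429 for TSPAN32, 0.0351 for CD200R1 and 0.0409 for C2. LYPD2, higher at porous disks at 4 weeks (log2 3.88), stood at −0.88 at 16 weeks (0.0484). Genes lower at porous disks at 16 weeks were COL6A6 (0.0429), SLITRK6 (0.0357), CDH19 (0.0493), FOLR2 (0.0493), and the complement genes C1QA (0.0389) and C1QB (0.0389). Genes higher there at 16 weeks were MBP (0.0351) and SLC22A3 (0.0493). None of these calls held in every alternative, since in edgeR the count was 0 with the keratinocyte score as a covariate and 0 without pig 16, 07, 08, 04 or 05. The gKOS minus control value differed between textures for 1 gene, HOXA10 (edgeR adjusted p = 0.0363), which cannot be told apart from a difference of device place.

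The first pattern is the texture effect at 4 weeks, 143 genes, among them KRT10 as higher and CD163, MARCO and VSIG4 as lower at porous disks. Without the 2 shallowest libraries 14 genes were called, so the count depended on them, yet their absence moved the median fold of the 143 genes only from 1.48 to 1.36 on the log2 scale (median SE 0.35 both times), and 142 still had an unadjusted p under 0.05. Leaving out the library of lowest collagen score gave 1.30 and 14 called genes. The folds of these 143 genes thus did not rest on the 2 shallowest libraries alone. The 143 were chosen with all libraries, most of which stay in, so a kept fold does not exclude chance. With the keratinocyte score as a covariate 0 genes were called in edgeR, 128 of the 143 had an unadjusted p under 0.05, and their median fold was 0.82 (median SE 0.33). The epidermal content of the dissected tissue may therefore account for part of this pattern, with KRT1 at 6316 ± 2260 CPM at porous and 475 ± 628 CPM at smooth disks (SD, n = 3 pigs), 3925 ± 2530 and 460 ± 643 CPM without the 2 shallowest libraries, which did not pass (edgeR adjusted p = 0.0642 and 0.194), and 0 list genes shared with another list, and whether texture itself changed that content stays open.

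The second pattern is the texture effect at 16 weeks, 1421 genes, among them 15 of 18 T cell genes as higher and 7 of 29 collagen and matrix genes as lower at porous disks. Devices 1 to 3 and 4 to 6 were taken as the sides. If row or side were the whole cause, the coated pairs and the control pair would run in opposite directions. Their fold changes instead correlated across genes at 0.283, 0.711 and 0.334 in pigs 81, 04 and 05, against that prediction. The same correlations were 0.331, 0.634 and 0.318 at 8 weeks, where edgeR called 0 genes. A positive value is therefore not particular to the 16-week genes, and the row or side is not ruled out. At 16 weeks the gKOS pair and the iKTN pair correlated with each other at only −0.197, 0.654 and −0.051. With the keratinocyte score as a covariate 1795 genes were called, 1414 of them among the 1421, which argues against keratinocyte content. Without pig 04 only 1 gene was called, and the median fold of the 1421 genes in the called direction was 1.55 on the log2 scale in pig 04, 0.58 in pig 81 and 0.79 in pig 05. A response of the tissue to the texture is a candidate explanation that was not tested apart from the device number, which never varied.

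Other splits of the texture labels within pigs and coatings were refitted, 25 with the real one. The averaged comparison had 3 splits as large (real 156, highest other 949), the one at 4 weeks 3 (143 and 1107) and the one at 16 weeks 2 (1421 and 2186), so chance could not be excluded for them. At 8 weeks all 25 were as large (0 and 1), which tests nothing where the real count is 0 in edgeR. For the average and for 4 weeks the highest split called several times the real count, and what set such a split apart was not tested. For the difference of the texture effect between times 1 split was as large (471 and 44). These splits shuffle each pair of a pig separately and remove the texture effect itself along with its change over time. They therefore cannot exclude chance for that change, which is seen only between pigs. The count of 471 fell to 0 in edgeR without any 1 of the pigs listed above.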

How the results depend on the processing

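The settings without the 2 shallowest libraries, without the library with the most detected genes, without the library of lowest collagen score and with a keratinocyte covariate were chosen after seeing the data, and the others were planned. Of 113 called results for named genes, 106 kept their direction in every alternative that tested the gene, and 8 also stayed past the threshold in each of those. They were HOXA10 in both coatings and at porous gKOS disks at 8 weeks, HOXA9 for iKTN, and CHRDL1, DLX2, ADAMTSL3 and GATA3 for texture. HOXA10 was not tested under the strict filter. Over all alternatives, values of called genes stayed past the threshold 1513 times, lost it 689 times in the same direction and reversed 8 times, while 27 results not called kept their side 475 times, passed 41 times and reversed 2 times. The depth limits the 2 shallowest libraries most. Apart from calls lost because a setting tests fewer genes or libraries, the cause was not tested.

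The reversed values were MOB2 for gKOS minus iKTN (0.08 without the 2 shallowest libraries, −2.91 to 0.10 with 1 pig left out) and for smooth iKTN at 4 weeks (−0.24, and −0.30 to 17.73), the values near 0 being those without pig 17, whose library holds the MOB2 counts. Over smooth control disks alone, CDSN (4.88), ASPRV1 (1.62), CST6 (5.36), KRTDAP (5.01), KRT80 (1.71) and PERP (3.27) reversed between 16 and 4 weeks, and 0 genes were called there in edgeR, as over both control disks summed (0).

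In counts of called genes, DESeq2 gave 66 for gKOS, 7 for iKTN, 11 between coatings and 976 for texture. Within single textures and times it gave 88, 8 and 17 (smooth gKOS at 4, 8 and 16 weeks), 88, 10 and 2 (smooth iKTN), 8, 3 and 143 (porous gKOS) and 9, 3 and 53 (porous iKTN). It gave 1111, 20 and 3084 for texture at 4, 8 and 16 weeks, 43 and 17 for gKOS and iKTN by texture, 8, 1 and 1877 for gKOS, iKTN and texture by time, and 746, 276 and 2186 for 8 against 4, 16 against 8 and 16 against 4 weeks. Limma-voom gave 4 for gKOS, 675 for texture, 0 and 2 for smooth iKTN at 4 and 16 weeks, 6 and 677 for porous gKOS at 8 and 16 weeks, 4 and 206 for porous iKTN at 8 and 16 weeks, 10, 216 and 6285 for texture at 4, 8 and 16 weeks, 4064 for texture by time, and 466 and 2243 for 8 and 16 against 4 weeks. With pigs as a random effect the time comparisons gave 762, 47 and 950.

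The strict filter, which left HOXA10 out, gave 1 for gKOS, 1 for iKTN, 0 for smooth iKTN at 8 weeks, 0 for porous gKOS and porous iKTN at 4 and at 8 weeks, 1 for porous iKTN at 16 weeks, 0 for gKOS by texture and 5 lists for 8 against 4 weeks. No filter gave 93 for texture, 34 and 802 at 4 and 16 weeks, 0 for gKOS by texture, 209 for texture by time, and 11, 4 and 572 for the time comparisons. DESeq2's size factors gave 0 for porous iKTN at 4 weeks and for gKOS by texture, and moved no median over all genes by more than 0.1.

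Pigs are paired by animal, and the fit with no replicate block gave 7 for smooth iKTN at 4 weeks, 0 for smooth iKTN at 8 weeks, 0 for porous gKOS and porous iKTN at 4 weeks, 0 and 1 for porous iKTN at 8 and 16 weeks, 55 and 926 for texture at 4 and 16 weeks, 0 for gKOS by texture, 1 for iKTN by time and 193 for texture by time; it moved no other count by over 1.5 times. A fit of 1 time alone gave 0 for smooth iKTN at 4 and 8 weeks, 0 for porous gKOS at 4 weeks, 0 for porous iKTN at 4, 8 and 16 weeks, and 2 and 6 for texture at 4 and 16 weeks, and 67 of 68 values of named genes lost the threshold there.

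Without the 2 shallowest libraries there were 72 for texture, 0 for smooth iKTN, porous gKOS and porous iKTN at 4 weeks, 5 for porous iKTN at 16 weeks, 14 for texture at 4 weeks, 0 for gKOS by texture and 264 for texture by time. Without the library of lowest collagen score there were 255 for texture, 0 for smooth iKTN at 4 weeks, 2 and 2 for porous gKOS at 8 and 16 weeks, 14 for texture at 4 weeks, 0 for gKOS by texture, 164 for texture by time and 750 for 16 against 4 weeks. Without the library with the most detected genes there were 0 for smooth iKTN at 8 weeks. With the keratinocyte covariate there were 23 for texture, 7 for smooth gKOS at 16 weeks, 1 and 6 for porous gKOS and porous iKTN at 16 weeks, 0 for texture at 4 weeks, 0 for texture by time and 9 lists between coatings.

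For gene lists, an estimated correlation and fry's directional test each called 0 lists in the 3 coating comparisons, the averaged texture comparison and the 3 time comparisons. For texture at 4, 8 and 16 weeks an estimated correlation called 0 lists each time, while fry, which asks whether a list moved on balance rather than more than other genes, called 3, 0 and 9.

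Leaving out 1 pig at a time gave 1 to 3 genes for gKOS (HOXA9 lost without pig 17), 2 for iKTN, 0 between coatings, 22 to 623 for texture, 0 to 136 for smooth gKOS at 4 weeks, 0 to 13 and 0 to 1 for smooth iKTN at 4 and 8 weeks, 0 to 1, 1 and 0 to 2 for porous gKOS at 4, 8 and 16 weeks, and 0 to 1, 0 to 1 and 0 to 8 for porous iKTN. It gave 3 to 437, 0 to 2 and 1 to 1790 for texture at 4, 8 and 16 weeks, 0 to 1 for gKOS by texture and by time, 0 to 1675 for texture by time, and 0 to 1, 0 to 2 and 0 to 758 for 8 against 4, 16 against 8 and 16 against 4 weeks. The lists called ranged from 13 to 20 (gKOS), 11 to 16 (iKTN), 3 to 11 (between coatings), 12 to 16 (texture), 8 to 15, 5 to 13 and 9 to 15 (time), and the correlation of the 2 coatings' fold changes from 0.362 to 0.743.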

Other observations

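The tests of the 2 shallowest libraries and of the device numbers, the exact test of HOXA9 alone, and the other splits within a single texture and time and over time were chosen only after the results were seen.

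Some gene groups were not described above. Schwann cell and nerve genes had a median log2 fold change of 0.81 at iKTN disks against control (camera adjusted p = 0.0022, adjusted p = 0.502 with an estimated correlation) and 0.92 between 8 and 4 weeks, with 5 passing when adjusted over the list alone (camera adjusted p = 0.000516, adjusted p = 0.748 with an estimated correlation). Mast cell genes had medians of 0.47 at gKOS disks (camera adjusted p = 0.0139, adjusted p = 0.35 with an estimated correlation) and 0.50 at iKTN disks (camera adjusted p = 0.00104, adjusted p = 0.433 with an estimated correlation). Blood haemoglobin genes, a sign of blood in the sample, had a median of −0.67 at porous disks in 5 of 5 members (camera adjusted p = 0.00616, adjusted p = 0.351 with an estimated correlation) and of −2.43 at 16 against 4 weeks (camera adjusted p = 0.00102, adjusted p = 0.587 with an estimated correlation). Hair follicle genes had a median of −3.15 at 16 against 4 weeks (camera adjusted p = 0.000697, adjusted p = 0.587 with an estimated correlation).

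The third pattern is the lower HOXA10 and HOXA9 at coated disks. Without the 2 shallowest libraries HOXA10 stood at −3.56 for gKOS against control, so they are not its cause. HOX genes keep positional identity in skin, and each disk type had the same device number in 9 of 9 pigs, so the coating and the place of the device cannot be told apart, although either could account for it. A place effect would turn with the order of gKOS and iKTN devices between textures. The order difference is gKOS minus iKTN on smooth disks less the same on porous disks. For a place effect it was predicted to be positive for paralog groups 9 and above and negative for 8 and below. Over HOX genes not examined before it averaged 0.653 (7 genes of 9 and above) and 0.109 (15 of 8 and below), so the second was not negative. These means differed by 0.544 ± 1.14 on the log2 scale (SD, n = 9 pigs, positive in 5 of 9, two-sided exact sign-flip p = 0.195), which leaves it open. The order difference of HOXA9 itself was 1.81 ± 1.47, positive in 8 of 9 pigs (two-sided exact sign-flip p = 0.00781), and that of HOXA10 was 1.59, positive in 8 of 9. Both genes had been looked at before. Median HOXA10 was 0.0411, 0.101 and 2.1 CPM at devices 1 to 3 and 0.157, 0.374 and 2.21 CPM at devices 4 to 6. Median HOXA9 was 1.08, 1.6 and 5.47 CPM and 1.23, 3.48 and 6.58 CPM. Both genes rose with device number within each set, in which devices 3 and 6 were the controls. Of the other HOX genes of paralog groups 9 and above, none passed for either coating against control. HOXA11 (log2 −1.08 for gKOS and −1.21 for iKTN), HOXC10 and HOXC11 had negative values for both coatings. HOXC9, HOXD9, HOXD10 and HOXD11 (log2 1.27 and 0.82) had positive values for both, and HOXC13 had 1.74 and −0.01. The fall was thus not common to the HOX genes of these groups.

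Other splits of the coating labels within pigs and textures were refitted, 25 with the real one. For gKOS against control 2 splits called as many genes (real 2, highest other 1415), so chance could not be excluded for that count. What set the highest split apart was not tested. For iKTN against control 1 was as large, the real split itself (real 2, highest other 0). No fewer is possible with 25 splits, and the outcomes were not adjusted over the comparisons, so chance was not excluded there either. For gKOS against iKTN 25 were as large (real 0, highest other 439), and for the gKOS effect by texture 1 was (real 1, highest other 0). These splits also remove the HOXA10 difference between gKOS and control disks itself, so they cannot exclude chance for its change with texture. The call of that 1 gene was lost without any 1 pig except pig 81. For iKTN by texture and for either coating by time all 25 were as large (real 0, highest other 0). Where the real count is 0, every split is as large and the comparison tests nothing.

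Within a single texture and time only 4 splits exist, too few for a share under 0.05. The real count of genes was from 0 to 2 and the highest other 0, except for smooth iKTN at 4 weeks (real 1, highest other 9). All 4 splits were as large in the comparisons with 0 genes and for that one, and 1 in the others. Over time 10 splits exist, also too few, with real counts of 0 (8 against 4 weeks, 10 as large, highest other 1), 0 (16 against 8 weeks, 10 as large, highest other 190) and 274 (16 against 4 weeks, 1 as large, highest other 0).

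The library of the smooth iKTN disk of pig 08 at 8 weeks had 23937 genes detected, against 20923 in the next.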
